A study of Mus musculus with 9 samples.

How the data were processed

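Whole genome bisulfite sequencing was done on 9 libraries of Cd1 mice carrying an αMHC-GFP reporter, in 3 groups of 3 biological replicates per the labels. Genomic DNA was sonicated, made into libraries with an Ovation Ultralow Methyl-Seq kit and sequenced in paired reads on a HiSeq 2000, per the labels' protocols. The tools FastQC, Picard and Bismark and the build mm9 are named in the submitters' processing notes, without versions, and their roles are not given in the sources used here. The authors deposited counts of methylated and of total reads for each of 43939965 cytosines, strands apart, per the deposited column names. They also deposited lists of differentially methylated regions (DMRs) for day 3 and day 7, with a mean difference and test scores per region, and a table with the nearest gene and the distance to its start site. The scores and mean differences are the authors' values, per the file headers, and the way the regions were called is not given in the sources used here. Each list file holds a first block that repeats part of the second; the second block was read.

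The counts of both strands were summed to 23497934 CpG sites. Depth ranged from 132183082 to 266545733 CpG calls per library, and between 85.6% and 89.4% of sites were covered. At this depth single sites are imprecise, so calls were summed over tiles, DMRs, or windows. The global level is the share of methylated calls at the 4736659 autosomal sites with at least 5 reads in every library. Tiles of 1 kb on autosomes and X entered the test with at least 4 CpG sites and 20 calls in every library. Of 2517153 tiles, 1681851 met this.

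Methylated and unmethylated calls were fitted with a quasi-binomial logistic model with all 9 libraries in one fit. The dispersion was moderated across regions by the empirical Bayes squeezing of limma, followed by an F test and Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 and a difference of at least 10 percentage points, and a DMR at an adjusted p under 0.05 over its list. The model was tested on simulated data of 100000 tiles with 2000 changed. For labelled day 7 against labelled fibroblasts, 4.94% of the calls were false, and 14%, 66.2% and 93.9% of the changes of 10, 20 and 30 points were recovered. For labelled day 3 against labelled fibroblasts 5.58% were false. The simulated spread was taken from the libraries labelled fibroblasts and day 3 only. The real day 7 libraries spread more, with a chi-square per tile of 5.4 for replicate 1 against replicate 2. The simulated rates therefore do not describe the real comparisons with day 7. Single values per library were compared with two-sided exact permutation tests, over all 1680 arrangements for 3 groups. Gene lists were compared with other DMRs by Fisher's exact test on direction, adjusted over the lists, which takes DMRs of a gene as independent. In a test added after the data were seen, each gene counted once by its share of lower DMRs, and a list's mean was compared with 100000 random sets of as many genes (two-sided permutation test). Read excess was tested with limma on log2 of reads per CpG over the library median, with a pseudocount of 0.1. A scan for loci with more reads in every library of a group used windows of 200 bp, in which the lowest library of the group lay above 2 times its median and above 2 times the highest other library.

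Named DMRs were, per time point, the 10 with the largest gain and the 10 with the largest loss among those past the test, with replicates apart, at least 20 calls in each library and a gene name. Up to 4 per gene list and any at Gata4, Mef2c, Tbx5 or Myh6 were added, together with the 3 tiles with the largest difference in each direction. A gene that this rule selects in the day 7 list is not reported here. These rules, the tests, the 15 gene lists and most of the other settings were fixed before the data were examined. The lists cover sarcomere and contractile genes, cardiac transcription factors, calcium handling and ion channels, energy metabolism, fibroblast and matrix genes, TGF-beta and BMP, Wnt, DNA methylation machinery, cell cycle, and markers of smooth muscle, endothelial, immune, epicardial, skeletal muscle and neural cells. A second list of 59 myeloid genes was written later. Gene names come from the deposited annotation, which gives the nearest gene at whatever distance, so a DMR said to be at a gene may lie far from it. The order of genes around Gata4 comes from a GRCm38 table, used for neighbours only. Promoters were not analysed here, because an annotation of mm9 was not used here.

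Alternatives were other call minimums, tile widths, thresholds and dispersion floors, a fit to the 6 compared libraries, calls thinned to equal depth, limma and edgeR, a term for the replicate number, and leaving out each library. Agreement of replicates was checked by a chi-square of calls per tile, which averaged 1.52 to 1.88 within groups, except 5.4 for labelled day 7 replicate 1 against replicates 2 and 3; no pair was as close as sampling noise alone. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.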

Results

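DNA methylation was measured by whole genome bisulfite sequencing in 9 libraries of cells from neonatal mouse heart. Per the labels, 3 libraries came from fibroblasts infected with a dsRed control retrovirus; the labels date them at day 7, while the series text calls fibroblasts the starting population. A further 3 came from cells sorted for an αMHC-GFP cardiac reporter at day 3 after infection with Gata4, Mef2c and Tbx5 retroviruses, the factors that turn fibroblasts into induced cardiomyocytes, and 3 from such cells at day 7. The control libraries held 217548013, 266545733 and 192961153 CpG calls, the day 3 libraries 132183082, 148242427 and 151028015, and the day 7 libraries 191726100, 198560210 and 209752387. The labels also give the groups different inhibitors and sort gates, and the deposited names of 2 of the 3 day 3 columns carry a suffix that no other column has. Infection, inhibitors, gate and any batch of the day 3 libraries therefore cannot be told apart from the groups.

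The delivered genes were examined first, because retroviral copies of their coding sequence can add reads over the endogenous exons. Reads over Tbx5, which encodes a cardiac transcription factor, were in excess in all 6 libraries labelled fibroblasts and day 3, and in none of the 3 labelled day 7. In the differentially methylated region (DMR) on chromosome 5 at 120332777 to 120333708 (mm9), reads per CpG reached 7.7, 7.0 and 15.9 times the library median in the libraries labelled fibroblasts. They reached 21.5, 8.5 and 7.5 times the median in those labelled day 3, against 0.9, 1.0 and 1.1 in those labelled day 7 (exact permutation test over 3 groups, p = 0.0214). A Mef2c DMR on chromosome 13 at 83731998 to 83732457 had ratios of 3.3, 1.5 and 19.9 in the libraries labelled fibroblasts, 10.3, 3.2 and 6.0 in those labelled day 3, and 1.1, 1.1 and 1.3 in those labelled day 7 (exact permutation p = 0.154). A window on chromosome 14 at 63859401 to 63860000, between DMRs annotated to Defb42 and Fam167a, which flank Gata4 in the gene order of GRCm38, had ratios of 13.2, 8.5 and 14.3, then 54.6, 15.3 and 8.7, then 1.9, 1.2 and 0.6 (exact permutation p = 0.0143). This window was singled out after its values were seen. The delivered genes thus go against the labels of the control and day 7 libraries, so groups are named below by their labels, and every direction given is a direction between labels.

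**Figure D1:**
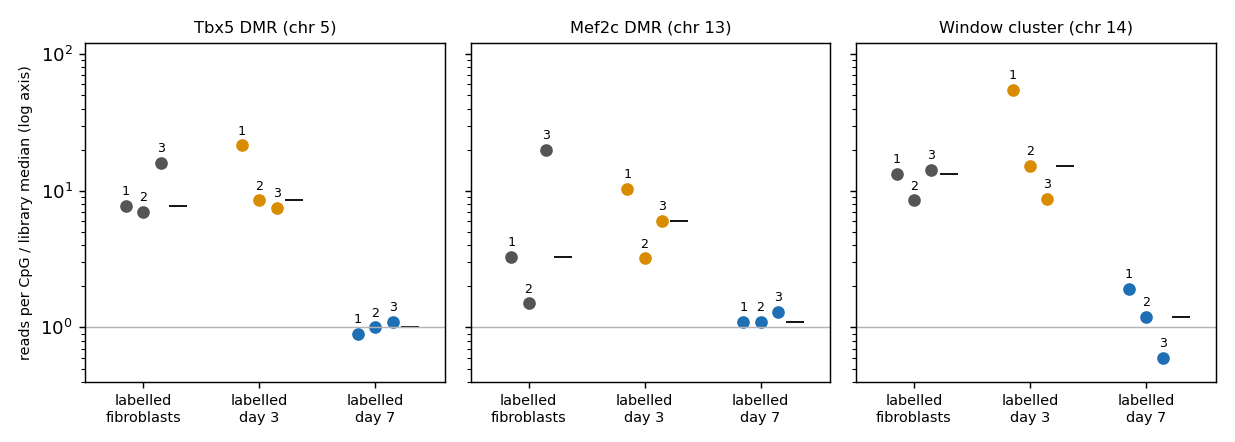
Reads per CpG divided by the library median (log axis) at a Tbx5 DMR, a Mef2c DMR and a chromosome 14 window, with 1 numbered point per replicate and a bar at each group median. At Tbx5 the libraries labelled day 7 lie between 0.9 and 1.1, and the other libraries between 7.0 and 21.5.

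Genome-wide CpG methylation was similar in the libraries labelled fibroblasts and day 3 and higher in 2 of the 3 labelled day 7. The level over autosomal sites was 74.7% ± 0.63 (SD, n = 3) for labelled fibroblasts, 74.0% ± 0.34 (SD, n = 3) for labelled day 3 and 76.9% ± 2.28 (SD, n = 3) for labelled day 7. Replicates 2 and 3 labelled day 7 reached 78.2% and 78.1%, while replicate 1 was at 74.2%. On the X chromosome the same libraries were at 73.4% and 73.5%, against 65.7% in replicate 1 and 68.2% ± 0.70 (SD, n = 3) in labelled fibroblasts. The groups did not differ beyond the spread between replicates (exact permutation test over 3 groups, p = 0.0893 for autosomes and 0.268 for X); without day 7 replicate 1 the autosomal p was 0.0107. A two-sided test of 3 against 3 libraries cannot go below 0.1. Sites over 80% methylated made up 57.4% ± 4.94 (SD, n = 3) of sites in the labelled day 7 libraries and 53.3% ± 1.24 (SD, n = 3) in labelled fibroblasts.

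**Figure D2:**
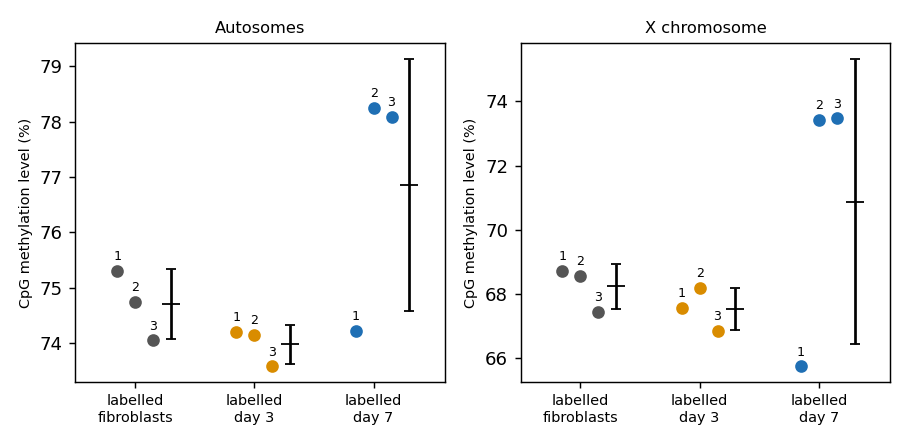
CpG methylation level in percent on autosomes and the X chromosome, with 1 numbered point per replicate and the mean ± SD beside each group. Replicates 2 and 3 labelled day 7 lie above the other libraries, at 78.2% and 78.1% on autosomes.

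Large domains followed the same pattern. In the 8070 windows of 100 kb under 70% methylated, the mean level was 63.0% ± 0.62 (SD, n = 3) for labelled fibroblasts, 62.6% ± 0.59 (SD, n = 3) for labelled day 3 and 65.8% ± 3.67 (SD, n = 3) for labelled day 7. Replicates 2 and 3 of the last group stood at 68.0% and 67.7% and replicate 1 at 61.5%. The 17480 windows at or over 70% stood at 76.7% ± 0.69, 76.1% ± 0.53 and 78.0% ± 1.97 in the same order (SD, n = 3). Neither class differed between groups in the exact permutation test over 3 groups (p = 0.232 and 0.2).

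Across 1 kb tiles the libraries fell apart in a way the labels do not describe. The libraries labelled fibroblasts, those labelled day 3 and day 7 replicate 1 correlated with one another at r = 0.818 to 0.889. Day 7 replicates 2 and 3 correlated at 0.880 with each other and at 0.667 to 0.706 with the rest. These correlations are across tiles, which are not independent replicates.

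**Figure D3:**
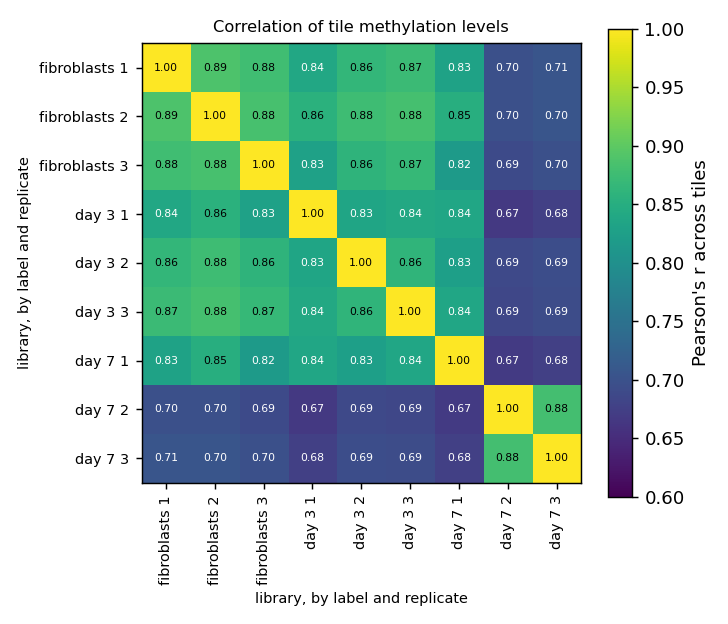
Pearson's r of tile methylation levels between all 9 libraries, named by label and replicate, on a colour scale from 0.6 to 1. Day 7 replicates 2 and 3 form a pair at 0.880, and their r with the other libraries lies between 0.667 and 0.706.

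The comparison of labelled day 3 with labelled fibroblasts asks which regions differ at the earlier time point, with controls that the labels date at day 7. No tile was called among 1681851 tested with the quasi-binomial model (smallest adjusted p = 0.826). In this model 47636 tiles had an unadjusted p under 0.05, which is 2.83%. limma and edgeR, also fitted to all 9 libraries, called 0. Such fits take in the spread of the labelled day 7 replicates, with a chi-square per tile of 5.4 for replicate 1 against replicate 2. A fit to the 6 compared libraries alone, which leaves that spread out, called 701 tiles, 68 higher and 633 lower. The count of 0 thus holds for fits that include the labelled day 7 libraries. In simulated data of this design, 57.9% of tiles changed by 20 percentage points were recovered among 100000 tiles. However, 5.12% of the unchanged simulated tiles had an unadjusted p under 0.05, more than the 2.83% of real tiles, so this recovery overstates what the count of 0 excludes.

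The comparison of labelled day 7 with labelled fibroblasts asks which regions differ at the later one. Methylation was higher in 31689 tiles and lower in 10956, together 42645 of those tested. The tile with the largest gain lay at Tbx5, on chromosome 5 from 120333001 to 120334000, at 25.3%, 31.5% and 9.1% in labelled fibroblasts and 87.8%, 87.2% and 92.2% in labelled day 7; extra reads cover this tile in the former. The next gains were on chromosome 11 at 16700001 (66.5 points) and on chromosome 5 at 144386001 (64.5 points). The strongest losses were on chromosome 8 at 85668001, which fell by 65.0 points, on chromosome 13 at 102293001, which fell by 63.6, and on chromosome 15 at 67177001, which fell by 60. The median size of the difference in called tiles was 13.6 points in day 7 replicate 1, 29.5 in replicate 2 and 29.1 in replicate 3. In replicate 1, 94.9% of called tiles had the group's direction. Replicate 1 entered the calls, so this share is partly fixed by the selection. With replicates 2 and 3 left out, an alternative added after the data were seen in which the lone library is assumed to vary like the others, 6431 tiles were higher and 6522 lower. The count was 302567 without day 7 replicate 1, 6153 without replicate 2, 5419 without replicate 3, and 7523, 8494 and 5621 without labelled fibroblast replicates 1, 2 and 3. edgeR called 9534 tiles (7787 higher, 1747 lower) and limma 0. A fit to the 6 compared libraries alone called 6704 (5730 higher, 974 lower), tiles of 2 kb gave 22842, calls thinned to equal depth 23173 and a minimum of 40 calls 27589.

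Between the time points, 3399 tiles were higher and 266 lower in labelled day 7 than in labelled day 3, together 3665. Of these, 3264 were also called in the same direction against labelled fibroblasts. The largest gains were the Tbx5 tile (74.3 points), a tile on chromosome 13 at 83802001 (64.7 points) and 1 on chromosome 15 at 77067001 (61.6 points). The Tbx5 tile held 16.09, 6.62 and 5.86 times the median reads in labelled day 3 and 0.9, 0.93 and 1.08 times in labelled day 7, so its level in the former mixes in the extra reads. The chromosome 13 tile, beyond the last DMR annotated to Mef2c (at 83748683), held 2.82, 2.56 and 14.07 times the median reads in labelled fibroblasts, 9.99, 3.95 and 4.52 times in labelled day 3 and 1.56, 1.19 and 1.05 times in labelled day 7, so its gain is open to the same extra reads. The strongest losses were on chromosome 11 at 81836001, which fell by 64.0 points, chromosome 5 at 139881001, which fell by 60.6, and chromosome 12 at 102014001, which fell by 59.4. The count was 276140 without day 7 replicate 1, 0 without day 7 replicate 2 or 3, 68 without day 3 replicate 1 and 0 without day 3 replicate 2 or 3. A fit to the 6 compared libraries alone called 2 tiles and a minimum of 40 calls gave 0, while a minimum of 10 calls gave 6167, tiles of 2 kb 629 and calls thinned to equal depth 17033. edgeR called 4 tiles and limma 0, and 247551 tiles had an unadjusted p under 0.05.

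The authors' deposited list for day 3 holds 305 DMRs, of which 148 were higher and 155 lower than in labelled fibroblasts when levels were recomputed from the counts. The authors chose these regions on these samples, so their direction is not independent evidence. In the higher DMRs the mean level was 36.2% ± 5.9 (SD, n = 3) in labelled fibroblasts, 60.3% ± 5.8 (SD, n = 3) in labelled day 3 and 69.9% ± 5.3 (SD, n = 3) in labelled day 7. In the lower DMRs it was 62.7% ± 2.2 (SD, n = 3), 35.7% ± 5.6 (SD, n = 3) and 57.7% ± 15.6 (SD, n = 3), with labelled day 7 replicates at 39.7%, 66.8% and 66.5%. Only 5 DMRs passed the region test, 1 higher and 4 lower. Methylation fell at AC132118.1 on chromosome 5, from 64.6% ± 7.4 to 23.0% ± 7.6 (SD, n = 3), at 9430038I01Rik on chromosome 7, from 65.5% ± 5.3 to 32.8% ± 6.9 (SD, n = 3), and at Gm10570 on chromosome 4, from 60.9% ± 0.3 to 32.9% ± 7.4 (SD, n = 3). It rose at 1700054M17Rik on chromosome 2, from 14% ± 3.1 to 43.0% ± 7.4 (SD, n = 3). Labelled day 7 stood at 15.6% ± 3.6 at 1700054M17Rik, near labelled fibroblasts (SD, n = 3). It stood at 24.5% ± 7.3 at AC132118.1, 12.4% ± 3.4 at 9430038I01Rik and 35.2% ± 4.5 at Gm10570 (SD, n = 3). The fifth, at the sarcomere list's dystrophin gene Dmd on the X chromosome at 81790746, fell from 75.5% ± 4.3 to 15.5% ± 3.7 (SD, n = 3), with labelled day 7 at 67.5% ± 16.7 (SD, n = 3). It holds as few as 6 calls in 1 library, so the naming rule left it out, and it was singled out after its values were seen. With any 1 of the 6 compared libraries left out the calls at Dmd (adjusted p 0.0768 to 0.16), Gm10570 (0.0865 to 0.175) and 1700054M17Rik (0.0768 to 0.175) were lost. The call at 9430038I01Rik was lost without labelled fibroblast replicate 1 (0.0652) or 3 (0.0577) or labelled day 3 replicate 1 (0.15) or 2 (0.061), and that at AC132118.1 without labelled fibroblast replicate 1 (0.0652) or labelled day 3 replicate 2 (0.061). With sites of at least 5 reads adjusted p was 0.083 at Gm10570 and 9430038I01Rik and 0.128 at 1700054M17Rik. limma called 0, and 110 DMRs had an unadjusted p under 0.05. A fit to the 6 compared libraries alone, added after the data were seen, called 130, 49 higher and 81 lower. Unlike that fit, the main one also takes in the spread of the labelled day 7 replicates. The count was 0 without labelled fibroblast replicate 1, 2 without replicate 2 and 1 without replicate 3; it was 1, 0 and 2 without labelled day 3 replicates 1, 2 and 3. Of the fixed gene lists, 5 held 7 of these DMRs, all with adjusted p = 1 for direction.

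The deposited day 7 list was far larger, with 9667 DMRs annotated to 5896 genes. Methylation was higher in 6685 and lower in 2974 in the libraries labelled day 7, and 8370 passed the test (5906 higher, 2464 lower; limma 8269). With sites of at least 5 reads 4883 passed. The list was likewise chosen on these samples. In the higher DMRs the mean level was 31.1% ± 3.1 (SD, n = 3) in labelled fibroblasts and 54.1%, 82.1% and 81.4% in the 3 labelled day 7 libraries. In the lower DMRs it was 78.7% ± 0.6 (SD, n = 3) in labelled fibroblasts and 71.4%, 18.8% and 19.8% in the same libraries. Replicate 1 thus carried part of the gains and little of the losses. Without replicates 2 and 3, an alternative added after the data were seen, 1844 DMRs were called higher and 151 lower; the lone library is assumed to vary like the others, and the list was chosen with it.

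**Figure D4:**
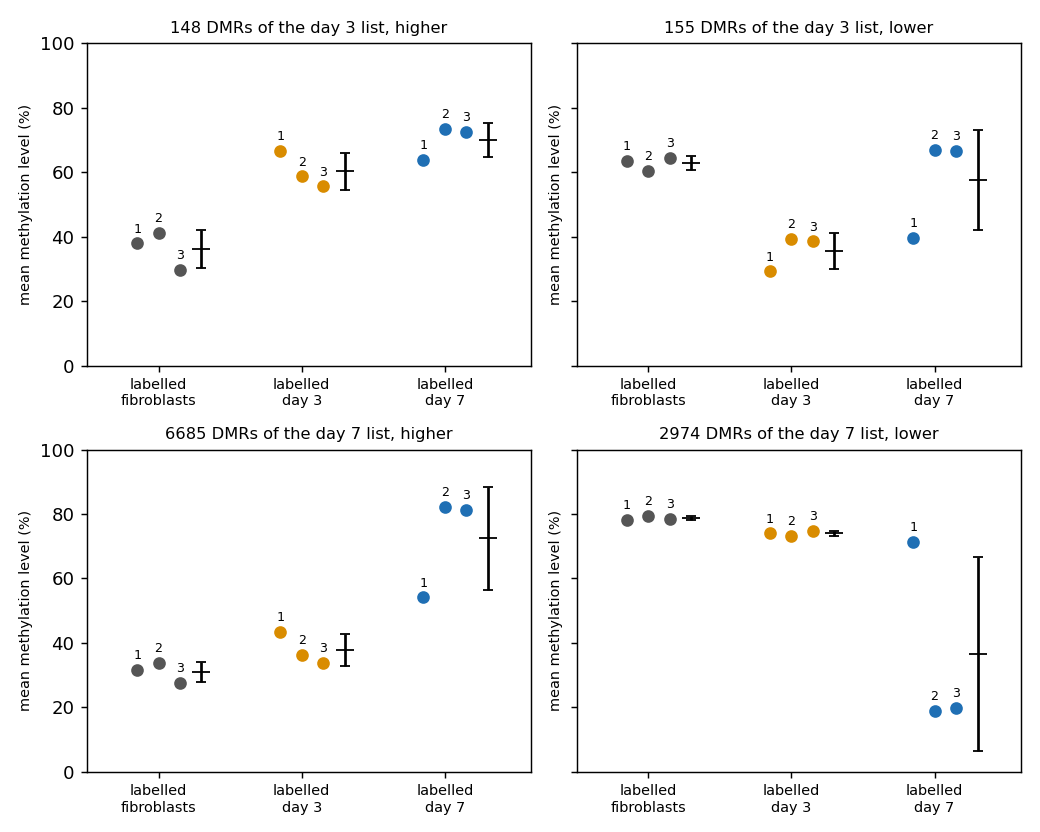
Mean methylation level in percent over the DMRs of each deposited list and direction, with 1 numbered point per replicate and the mean ± SD beside each group. In the lower DMRs of the day 7 list, replicates 2 and 3 labelled day 7 are at 18.8% and 19.8% and replicate 1 is at 71.4%.

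The largest gains among named day 7 DMRs were at Gm10287 (69.4 points), Cyth3 (69.1), Tbx5 (68.7), Rapgef1 (67.3), E230015J15Rik (66.5), Cttnbp2nl (66.4), 2310079F23Rik (66.0), Umps (65.7), Prrx1 (65.6) and Mcl1 (65.2). Labelled fibroblasts held 7.0 to 15.9 times the median reads at this Tbx5 DMR. At Prrx1, a mesenchymal homeobox gene, the level rose from 16.7% ± 3.8 to 82.4% ± 21.2 (SD, n = 3), 1060.5 bp from the start site. At Cttnbp2nl it rose from 28.1% ± 5.9 to 94.5% ± 4.7 (SD, n = 3). The DMRs that lost most were at Wasl, Itm2b, Adck1, n-R5-8s1, Reep3, Rnpep, Kcnk13, Arid5b, SNORA17 and Dna2. At Wasl the level fell from 96.7% ± 4.2 to 30.4% ± 48.5 (SD, n = 3), with labelled day 7 replicates at 86.3%, 0.0% and 4.9%. At Arid5b, 144563.5 bp from the start site, the replicates were at 74.6%, 3.3% and 3.0%, against 88.5% ± 3.1 (SD, n = 3) in labelled fibroblasts. The call at Dna2 was lost without labelled fibroblast replicate 2 (adjusted p = 0.0519) and with sites of at least 5 reads (0.0653).

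Sarcomere and contractile genes had no lower DMR in the day 7 list. All 19 DMRs annotated to them, at 11 of 41 genes, were higher in the libraries labelled day 7, whereas 30.9% of other DMRs were lower (Fisher's exact test, p = 0.00172; adjusted p = 0.0258). That test takes DMRs of a gene as independent; with each gene counted once, in a permutation test added after the data were seen, the list did not pass (p = 0.00694; adjusted p = 0.104). All 19 passed the test, also when adjusted over the list alone, and 18 were higher in replicate 1. The deposited list was chosen on these libraries, and 5906 of its 6685 higher DMRs passed, so neither count is particular to sarcomere genes. The mean level of the 19 DMRs was 29.2%, 30.9% and 27.7% in labelled fibroblasts and 37.7%, 33.9% and 33.6% in labelled day 3. In labelled day 7 it was 52.8%, 84.5% and 84.0%, much as in all higher DMRs (54.1%, 82.1% and 81.4%). Methylation rose at Pdlim5 from 30.5% ± 4.6 to 87.6% ± 9.8, at Tmod1 from 19% ± 1.8 to 73.6% ± 34.2, at the atrial myosin light chain gene Myl4 from 36.6% ± 16.8 to 87.6% ± 5.8, and at Myom2 from 6.3% ± 1.9 to 56.1% ± 38.5 (SD, n = 3). These DMRs lay 184201, 3103, 5505.5 and 12888.5 bp from the start sites, in that order. With sites of at least 5 reads the call at Myl4 was lost (adjusted p = 0.13).

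Other cardiac lists did not pass Fisher's exact test on direction. Cardiac transcription factors had 37 higher and 9 lower DMRs (adjusted p = 0.275, Fisher's exact test); 35 passed the test both ways, as they did when adjusted over the list alone. Mef2c on chromosome 13 at 83620155 rose from 17.1% ± 5.2 to 79.0% ± 22.0, Meis1 from 14.8% ± 6.8 to 71.6% ± 27.1 and Hand2 from 8.7% ± 2.4 to 64.4% ± 34.8 (SD, n = 3). Their distances from the start sites were 22712, 2341 and 341656.5 bp, in that order. The list included 4 DMRs at Mef2c, of which 3 rose and that at 83748683 fell by 52.7 points (adjusted p = 0.0103), with labelled day 7 replicates at 94.6%, 5.1% and 21.1%. Of 4 at Tbx5, 3 rose and that at 120273642 did not pass (9.0 points, adjusted p = 0.621). The rises at 83731998 (Mef2c) and 120332777 (Tbx5), which are among the 37 higher DMRs, lie under the extra reads given above, so their levels in labelled fibroblasts mix these in. Neither list had a DMR at Gata4 or Myh6. Genes of calcium handling and ion channels had 20 higher and 4 lower (adjusted p = 0.343), with gains of 49.8 points at Jph2 and 46.6 at Gja5, while Camk2d fell by 49.2. Energy metabolism genes had 8 higher and 1 lower (adjusted p = 0.436), with gains of 48.7 points at Acsl1, 38.7 at Pdk4, 34.8 at Mb and 34.4 at Ckmt2. The call at Ckmt2 (adjusted p = 0.032) was lost without any 1 of the 3 labelled fibroblast libraries (0.0547, 0.0827 and 0.0706), without labelled day 7 replicate 2 (0.0688) or 3 (0.13), and with sites of at least 5 reads (0.441).

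Fibroblast and matrix genes leaned to gains, with 34 higher and 5 lower DMRs, short of the threshold (Fisher's exact test, adjusted p = 0.0705). Besides Prrx1, Meox1 gained 59.1 points, Col6a1 49.1 and Postn, which encodes periostin of activated fibroblasts, 47.3. TGF-beta and BMP genes had 17 higher and 9 lower (adjusted p = 0.778), with gains at Smad1 (62.8 points), Smad5 (52.4), Acvr1 (49) and Tgfb2 (48.2). Wnt genes had 20 higher and 4 lower (adjusted p = 0.343), with gains at Ror1 (53.5), Tcf7l2 (52.5), Wnt5a (52.2) and Rspo2 (48.5). The Rspo2 DMR lay 146457 bp from the start site. Genes of the DNA methylation machinery had 9 higher and 2 lower (adjusted p = 0.71), with gains at Gadd45g (55.2), Dnmt3a (51.6), Mbd2 (41.8) and Tet1 (41.2). The call at Tet1 was lost without labelled fibroblast replicate 1 (adjusted p = 0.0522) or labelled day 7 replicate 2 (0.0695) or 3 (0.0687), and that at Mbd2 with sites of at least 5 reads (0.161). Cell cycle genes had 5 higher and 7 lower (adjusted p = 0.211); Mki67 rose by 57.2 points and Rb1 fell by 51.7. In each list of this paragraph the mean gain and the mean loss were larger in labelled day 7 replicates 2 and 3 than in replicate 1, as at Meox1 (24.2%, 88.6% and 85.1%).

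Markers of other cell types moved in different directions. Immune markers had 1 higher and 5 lower DMRs, against 30.8% lower among others (Fisher's exact test, p = 0.0123; adjusted p = 0.0705). Methylation fell at the microglial and monocyte chemokine receptor gene Cx3cr1, from 60.7% ± 7.2 to 21.5% ± 17.6, and at the monocyte gene Cd14, from 53.2% ± 9.7 to 21.2% ± 4.8, and rose at Runx1, from 49.2% ± 8.4 to 83.5% ± 8.4 (SD, n = 3). The call at Cd14 (adjusted p = 0.0397) was lost without labelled fibroblast replicate 1 (0.0765), 2 (0.141) or 3 (0.0595) and without labelled day 7 replicate 2 (0.0942) or 3 (0.0739). The mean of the lower immune DMRs was 39.4% in labelled day 7 replicate 1 and 13.3% and 13.8% in replicates 2 and 3. Endothelial markers had 9 higher and 7 lower (adjusted p = 0.436), with Tek up by 47.0 points and Cdh5, which fell by 40.3. Smooth muscle markers had 7 higher and 3 lower (adjusted p = 1), epicardial 2 and 2 (0.74), neural 1 and 3 (0.269) and skeletal muscle 1 and 0 (1). Aldh1a2, an epicardial marker, fell by 45.3 points, and Ngfr, a neural one, fell by 34.9.

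Whether regions of the day 7 list already differed at day 3 was asked within that list. No DMR passed the region test between labelled day 3 and labelled fibroblasts among 9659 (quasi-binomial model). An unadjusted p under 0.05 in this model was reached by 215. The sign of the day 7 difference was shared by 74.0%, where 50% was simulated. However, the same fibroblast libraries served to choose the list and as controls of day 3. This alone can raise the share above 50% and shift the mean differences below, so neither shows an early change. In higher DMRs the labelled day 3 mean was 37.8% ± 4.9 (SD, n = 3), which is 6.7 points above labelled fibroblasts (exact permutation p = 0.2; simulated 0.22 points) and 4.0 points above without labelled day 3 replicate 1 (exact permutation p = 0.3). In lower DMRs it fell by 4.6 points to 74.0% ± 0.7 (SD, n = 3; exact permutation p = 0.1, the smallest possible). From labelled day 3 to labelled day 7, 5525 DMRs changed, 4131 higher and 1394 lower. That count was 2809, 0 and 0 without labelled day 3 replicates 1, 2 and 3, and 8772, 1290 and 1142 without labelled day 7 replicates 1, 2 and 3. Of the 305 day 3 DMRs, 82 overlapped the day 7 list, or 26.9%.

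Across tiles, the differences of labelled day 3 and labelled day 7 from labelled fibroblasts correlated at r = 0.303, against 0.442 simulated for unchanged groups with shared controls. The covariance was 15.1, beside a simulated covariance of 11.9. Shared controls add the variance of the fibroblast mean to this covariance, which was 12.3, so they can account for most of it. The 3 control libraries cannot be split with 2 on each side to remove this. With day 7 replicates taken singly r was 0.375, 0.184 and 0.187.

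The coverage scan looked for loci where all reprogrammed libraries gained or lost reads. By limma, 1 of 2149817 tiles had more reads in the 6 libraries labelled reprogrammed (chromosome 5 at 83335001) and 1 had fewer (chromosome 10 at 16541001), and neither lies at a delivered gene. The first held 0.0, 0.03 and 0.0 times the median reads in labelled fibroblasts and the second 0.0 in all 6 other libraries, and with a pseudocount of 1 both calls were lost. The count was 0 without labelled fibroblast replicate 1 or 3 and 1 without day 7 replicate 1. In a comparison added after the data were seen, 14 tiles separated the libraries labelled day 7 from the other 6, 8 with more reads and 6 with fewer. Among the other groups of 3 libraries drawn, labelled day 7 replicates 2 and 3 gave 21 tiles with day 3 replicate 1 and 21 with day 3 replicate 3, so 14 is not beyond other groupings. The Tbx5 tile, at a log2 ratio of -2.92 (adjusted p = 0.00136), and the chromosome 14 tile at 63859001, at -3.57 (adjusted p = 0.0116), were among those with fewer reads.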

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

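The tests of explanations in this part, the second myeloid list and the bounds for the counts of splits were written down after the results were seen; the comparisons between groups were planned.

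Extra reads lie over Tbx5 in the libraries labelled fibroblasts and day 3, and the libraries labelled day 7 lack them. A duplication of the locus in the animals is argued against by the flanks within 50 kb, where the ratio of the 6 libraries to those labelled day 7 was 1.02, beside 10.4 in the windows themselves. Coverage bias of CpG-rich windows is argued against by a ratio of 1.03 in matched windows. Labels of the control and day 7 libraries exchanged before deposit is a candidate explanation that the Tbx5 reads prompted and that stays open: at the Mef2c DMR 5 of the 6 libraries of both groups were out of place against a bound of 2 times the median, labelled fibroblast replicate 2 being at 1.5. If so, labelled day 7 against labelled fibroblasts would turn, with all 19 sarcomere DMRs lower in reprogrammed cells, and the comparisons with labelled day 3 would be of other groups than their labels say.

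Replicates 2 and 3 labelled day 7 stand apart from replicate 1 across the genome. Incomplete bisulfite conversion is argued against by the mitochondrial level, which was lower in both than in replicate 1 (difference for the higher of them -0.4 percentage points). Unequal depth is argued against by thinning every tile to equal calls, after which the correlation of replicates 2 and 3 (0.836) still exceeded that with replicate 1 by 0.193. Myeloid cells in replicates 2 and 3 were a candidate source that the next test cannot decide. In the second list of 59 myeloid genes, none of them in a fixed list, 21 of 34 DMRs at 19 genes were lower. With each gene counted once the share was 73.7% against 32.7% over all genes (permutation p = 0.00012). The genes were listed after the results were seen, and their DMRs come from a list chosen on these libraries. The direction is that of all 3 replicates together, so it does not separate replicate 1 from the others. The 21 lower DMRs averaged 73.5%, 17.6% and 16.0% in replicates 1 to 3. All lower DMRs share such levels (71.4%, 18.8% and 19.8%), so the levels say nothing of myeloid cells. A sort for αMHC-GFP may exclude such cells, but the purity of the sorts was not tested here, and fibroblasts may use some of these genes. The labels give the replicates the same stage of reprogramming, so the labelled stage does not set replicate 1 apart. Whether the libraries differ in how far reprogramming went was not tested.

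The test of the difference between time points called 3665 tiles and 5525 DMRs of the day 7 list. For tiles, 4 of the 10 splits of the 6 libraries gave as many, the highest other being 31462; the splits above the real one keep day 7 replicates 2 and 3 on 1 side, which points to a structure of the samples. For the DMRs, the real split was 1 of the 10 with as many and the highest other gave 2422; the list was chosen on the labelled groups, so other splits were bound to give fewer.

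Splits of 3 against 3 libraries number 10, too few for a share under 0.05. Labelled day 7 against labelled fibroblasts gave 42645 tiles, the highest other split 5604. The day 7 list gave 8370 DMRs and the day 3 list 5, the highest other 0 in both, which the choice of the lists on these groups fixes and which says nothing of chance. Labelled day 3 against labelled fibroblasts gave 0 tiles (highest other 1) and 0 DMRs of the day 7 list (highest other 1), so all 10 splits reached the real value. In the coverage scan, 8 of 50 splits gave at least the 2 tiles of the real one, with a highest other of 21, so chance is not excluded.

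Mitochondrial reads per site reached 557.2 times the autosomal median in labelled day 3 replicate 1, beside 151.7 to 234.4 in labelled fibroblasts, 239.6 and 196.4 in day 3 replicates 2 and 3, and 141.1, 51.5 and 56.2 in labelled day 7. In 15 of 5772301 windows of 200 bp, every library labelled day 3 was above 2 times its median and above 2 times the highest other library, beside 10 such windows for fibroblasts and day 7, 9 for fibroblasts and day 3, 5 for day 7, 3 for fibroblasts and 0 for day 3 and day 7. Of the 9 for fibroblasts and day 3, 5 lay nearest to DMRs of Tbx5 and 3 in the chromosome 14 window given above. The remaining one lay on chromosome 1 at 91110201. The 15 for day 3 fell in 14 separate places and the 10 for fibroblasts and day 7 in 6.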

How the results depend on the processing

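Alternatives named here as added, leaving out day 7 replicates 2 and 3 together, the 6-library fits of DMR lists, counting each gene of a list once, and leave-outs of the coverage scan, were chosen after seeing the data. Global and large-window differences kept their direction under each alternative tried, but 3 against 3 libraries cannot pass 0.05. Leaving out day 7 replicates 2 and 3 together was not tried for them. Day 7 replicate 1 lay below the labelled fibroblast mean on autosomes (74.22% and 74.71%). It also lay below in windows under 70% (61.51% and 62.99%) and at or over 70% (75.72% and 76.66%). The higher level of labelled day 7 than of labelled fibroblasts thus rests on replicates 2 and 3. The 3-group p for the global level ranged from 0.0107 (without day 7 replicate 1) to 0.164 with 1 library left out. For named DMRs, 495 of 549 alternatives left them on the same side of the threshold and 54 ended the call, with 0 reversed. Of the 54, 30 came from 38 alternatives of the 5 named day 3 DMRs (7 of 7 at Dmd and 8 of 8 each at Gm10570 and 1700054M17Rik, where adjusted p with the replicate block was 0.0655, 0.0655 and 0.0673) and 24 from 511 of the 65 named day 7 DMRs, 6 each at Ckmt2 and Cd14 (0.061 with the block); of the gene lists, the sarcomere list of day 7 was the 1 with a call to lose, which it kept among called DMRs (adjusted p = 0.0272) and lost with each gene counted once (0.104), when 0 lists passed.

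For tiles of day 7 against fibroblasts (42645), at least 40 calls gave 27589, which tests fewer tiles, 2 kb tiles 22842, thinning 23173, the fit to 6 libraries 6704, edgeR 9534 and limma 0; single leave-outs ranged from 5419 to 302567, and without both day 7 replicates 2 and 3 the count was 12953. For day 7 against day 3 (3665), at least 10 calls gave 6167, at least 40 calls 0, 2 kb tiles 629, thinning 17033, the fit to 6 libraries 2, edgeR 4 and limma 0; single leave-outs ranged from 0 to 276140, and without both replicates the count was 1863. Day 3 against fibroblasts stayed at 0 except for 701 in the fit to 6 libraries, the only alternative without the labelled day 7 libraries. The leave-outs lower the residual degrees of freedom, which does not account for the rises to 302567 and 276140. Those came without day 7 replicate 1. Its chi-square per tile was 5.4 against replicates 2 and 3, beside 1.77 for replicate 2 against 3, so leaving it out lowers the spread within the group. Otherwise the cause was not tested.

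Of the day 3 DMRs (5), sites with at least 5 reads gave 0, limma 0, single leave-outs 0 to 2 and the fit to 6 libraries 130. Of the day 7 DMRs (8370), sites with at least 5 reads gave 4883, and leaving out both replicates 1995. Day 3 differences in day 7 DMRs (0) ranged from 0 to 6 with 1 library left out and reached 1 in the fit to 6 libraries. Day 7 against day 3 in these DMRs (5525) ranged from 0 to 8772, and was 51 without both replicates, when the lone library is assumed to vary like the others. The coverage scan (2) gave 0 with a pseudocount of 1, 0 to 3 with 1 library left out and 14 for day 7 against the other 6. The cause was not tested.

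The replicate numbers did not clearly pair the samples. Same-numbered libraries deviated with r = 0.0, -0.026 and 0.03 for labelled fibroblasts and day 3. For fibroblasts and day 7 r was -0.026, -0.05 and 0.028, and for day 3 and day 7 it was 0.077, 0.052 and 0.011. Libraries of other numbers gave -0.07 to 0.067 over all groups. Deviations from a mean of 3 libraries depend on one another, so a pairing is not excluded. With the replicate block, tiles of day 7 against day 3 numbered 14020, of day 7 against fibroblasts 51638, and day 3 DMRs 2; day 7 DMRs numbered 8052. Promoters were not run. The 132183082 calls of the shallowest library limit what could be found at single sites.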

Other observations

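The shares near start sites were computed after the data were seen. DMRs of the day 7 list that were lower in the labelled day 7 libraries lay nearer to genes than those that were higher: 312 of 2974 (10.5%) and 456 of 6685 (6.8%) were within 1 kb of a start site (Fisher's exact test, p = 1.85e-09). The median distances were 11104.75 and 19961.0 bp. Neighbouring DMRs are not independent, and the list was chosen on these libraries. In the day 3 list the shares were 15.5% of lower and 8.1% of higher DMRs (p = 0.0521, Fisher's exact test).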
